A study of Mus musculus with 4 samples.

How the data were processed

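Per the series title, gene expression was measured by bulk RNA sequencing, in 4 libraries of GFP-positive, tdTomato-positive cells sorted from mouse femurs, 2 Hes1-derived and 2 Fgfr3-derived. Per the labels, RNA was amplified with a SMARTer kit, libraries were made with Nextera XT and sequenced on an Illumina HiSeq instrument. The extraction protocol in the labels instead names a sort for tdTomato alone and a single-cell 10X Chromium loading; since each library is a single column of counts, the values were treated as bulk, and which sort applies is left open. The same protocol says that the distal growth plates were removed. The submitters' processing notes name FastQC, TopHat2 2.0.13, Bowtie2 2.2.1, Cufflinks, Cuffdiff, HTSeq and DESeq2 and the mouse build mm10, without their order or role. The annotation and the strand setting of the counting are not given there.

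The deposited counts are whole read numbers for each gene symbol and library, made by the authors with the tools above per the submitters' processing notes. The deposited signal values are gene counts divided by a size factor: within each library every value was the count multiplied by a single constant. The deposited log2 values are a regularized log2 of the same counts, per the file names. Counts were used for all main tests, the depth-normalized signal for an alternative test, and the log2 values for differences between libraries.

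The count table had 17230 rows, each with at least 2 reads over the libraries, and 16955 of them matched a GENCODE M21 gene (build GRCm38), which gave the gene positions. Totals were 22745128 and 23625327 reads in Hes1-derived replicates 1 and 3, and 26025607 and 26804832 in Fgfr3-derived replicates 2 and 3, with reads on 15931, 16038, 16214 and 16221 genes. The filter of edgeR (minimum count 10) kept 14330 genes that held 99.96% of the counts in each library. The biological coefficient of variation was 27.8%.

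Hes1-derived were compared with Fgfr3-derived libraries with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3), with TMM factors and robust dispersions, and adjusted by Benjamini-Hochberg with a threshold of 0.05. Log2 fold changes are Hes1-derived minus Fgfr3-derived. Standard errors are the absolute log2 fold change divided by the square root of F, and ± after CPM is the SD of 2 libraries. With 2 libraries per group the fit has 2 residual degrees of freedom before information is shared across genes. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), in a family of 20 biology lists and a family of 14 lists of other cell types and quality, with Benjamini-Hochberg adjustment within each. Camera with an estimated correlation and fry, which tests whether a list moves 1 way, were run beside it. Counts "adjusted over the list alone" repeat the adjustment over the members of a list only.

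The lists, the main test, the alternatives and the rule for naming genes were fixed before the data were examined, except where stated. The rule names the 15 genes with the smallest p in each direction, leaving out predicted or unnamed genes. It adds up to 4 members of each list and direction with the smallest p, else the 2 most abundant members. It also names Hes1, Fgfr3, Cxcl12, Lepr, Kitl, Xist and 4 Y-linked genes whatever their test, the 2 most abundant members of each list of other cells, and the 5 genes with the most reads in each library. Some genes that the rule names are not reported. Of 1003 list entries 137 had no row, and 18 were matched by an older symbol. Neither mitochondrially encoded nor cytosolic ribosomal protein genes had a row (0 members matched), so that these quality lists were not analysed here.

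The alternatives were RLE, upper-quartile and library-total scaling, DESeq2 1.42.0, limma-voom, limma-trend on the deposited signal, both other filters, dispersions without robust estimation, an adjusted p under 0.10, a 2-fold minimum, the removal of genes of other cells, and leaving out each library. Scaling to the stroma list (27 members), scaling to eGFP reads and a pan-leukocyte covariate were chosen after seeing the data, when blood-cell markers were found to differ between the groups. The stroma list is the preset list of CXCL12-abundant reticular (CAR) cell genes without Ebf1, so under that scaling its members are set against their own mean. The labels give no strand setting, so reads of Sstr2, Ms4a1, Timp1, Ccl6, Col18a1, Hoxa11, Kif7, Lgr5, Mfap4, Cdk2, Ube2c, Cyp51, Alas2, Cytip, Abcc9, Arhgdib, Eng, Mylk and Xist may include those of a gene on the opposite strand.

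The tests were tested on simulated data with the real library sizes. Among 14330 genes, edgeR recovered 19 of 100 genes changed 2-fold and 70 of 100 changed 4-fold with 5 false calls, DESeq2 38 and 80 with 25 false calls, and voom 14 and 63 with 3 false calls. Camera called the shifted list and 0 of 20 unchanged lists. The simulated genes were independent, so this does not show how camera behaves when the genes of a list move together. In the real data the estimated correlation ranged from −0.20 (skeletal muscle markers) to 0.91 (pan-leukocyte markers). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.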

Results

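Bulk RNA sequencing was run on stromal cells sorted from the femurs of mice at postnatal day 21. The cell type labels give GFP and tdTomato as the marks of the sort. The extraction protocol names tdTomato alone, so whether GFP was also gated is open. GFP reports expression from the Cxcl12 locus and marks CXCL12-abundant reticular (CAR) cells, the marrow stromal cells that make factors for blood stem cells. tdTomato is a permanent lineage mark, switched on by a tamoxifen-dependent Cre after a pulse at embryonic day 12.5. In 1 group the Cre was expressed from Hes1 and in the other from Fgfr3, and the series title sets fetal perichondrium against chondrocytes as the 2 origins. The groups are called Hes1-derived and Fgfr3-derived here. Each group had 2 libraries, numbered replicates 1 and 3 for the Hes1-derived cells and replicates 2 and 3 for the Fgfr3-derived cells. The labels used here do not say whether a library came from 1 animal or from a pool.

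The libraries were of similar depth. Hes1-derived replicates 1 and 3 held 22745128 and 23625327 counted reads, and Fgfr3-derived replicates 2 and 3 held 26025607 and 26804832. The count table had 17230 rows, of which 14330 passed the low-count filter, and 3 of the rows were the transgenes eGFP, iCre-ERT2 and tdTomato-WPRE. Ngp, a neutrophil granule gene, took the most reads in both Hes1-derived libraries, with 0.897% of counts in replicate 1 (95% exact binomial interval 0.893% to 0.901%) and 1.07% in replicate 3 (1.07% to 1.08%). Mmp13, the gene of collagenase 3, took the most reads in both Fgfr3-derived libraries, with 1.18% in replicate 2 (1.18% to 1.19%) and 1.17% in replicate 3 (1.17% to 1.17%). These intervals cover counting error only. On the deposited regularized log2 scale, the root mean square difference across tested genes was 0.307 between the Hes1-derived libraries and 0.362 between the Fgfr3-derived libraries, against 0.478 to 0.664 for the 4 pairs across groups.

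The comparison asks how CAR cells of these 2 fetal origins differ in the marrow of young mice. Osteoblast-lineage genes were lower in the Hes1-derived libraries, while B lymphocyte, erythroid and cell cycle genes were higher. These list differences passed camera with its preset correlation, but with an estimated correlation the adjusted p was 0.418 for the osteoblast and cell cycle lists and 0.364 for the B lymphocyte and erythroid lists. Spp1, which encodes the bone matrix protein osteopontin, stood at 516 ± 87.9 CPM (counts scaled to library size; SD, n = 2) in Hes1-derived and 6788 ± 573 CPM in Fgfr3-derived libraries, a 13.2-fold difference. Mmp13 stood at 1090.4 ± 54.4 CPM against 12057 ± 88.1 CPM, an 11.1-fold difference. In the other direction, Ms4a1, the gene of the B-cell surface protein CD20, stood at 142 ± 20.04 CPM against 27.6 ± 7.47 CPM, and the proliferation gene Mki67 at 293 ± 18.6 CPM against 109.6 ± 3.99 CPM.

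With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over 14330 genes, 751 genes were higher and 940 lower in Hes1-derived libraries, so that 44.4% of the calls were higher. At least 2-fold differences made up 668 of the higher and 874 of the lower calls. For all 1691 called genes both libraries of a group lay on the same side of both libraries of the other group. This also held for 61.9% of all tested genes, where chance alone gives 33.3%. The split between higher and lower depended on the scaling. Scaling to the reticular stroma list moved the median gene up by 0.53 (log2) and gave 688 higher and 102 lower genes (87.1% higher), and scaling to eGFP reads moved it up by 0.84 and gave 324 higher and 19 lower genes (94.5% higher). With the pan-leukocyte level of each library as a covariate, 4 genes were higher and 4 lower. This covariate correlates with the group (r = 0.897) and leaves fewer residual degrees of freedom. A loss of calls would follow from that alone, so it does not show that leukocyte RNA accounts for the differences. The counts were 432 higher and 843 lower without Hes1-derived replicate 1, 243 and 181 without Hes1-derived replicate 3, 183 and 301 without Fgfr3-derived replicate 2, and 1225 and 998 without Fgfr3-derived replicate 3.

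**Figure D1:**
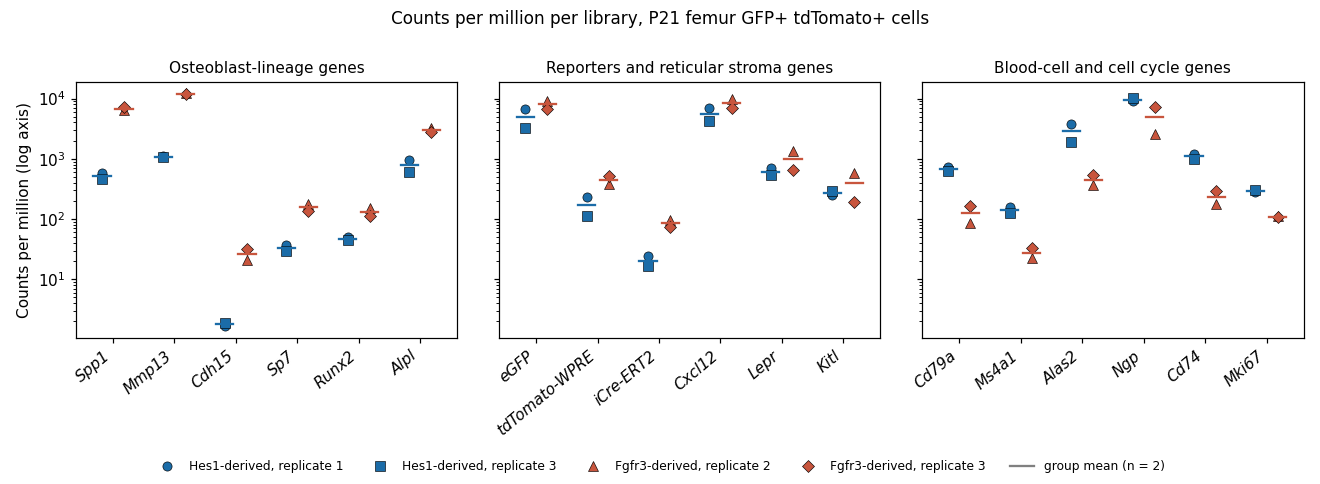
CPM on a log axis for 18 genes in each of the 4 libraries, with symbols for single libraries and a bar for each group mean (n = 2). Spp1 lies at 578 and 454 CPM in the Hes1-derived and at 6382 and 7193 CPM in the Fgfr3-derived libraries, while Cxcl12 and Lepr overlap between the groups.

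The 15 lower genes with the smallest p were between 4.01-fold and 18.4-fold lower, each with an adjusted p of 0.013. They were Sstr2 (a somatostatin receptor), Tubb6 (a beta tubulin), Rgs4, Timp1 (an inhibitor of metalloproteinases), Cdh15 (M-cadherin), Sema3a (a secreted guidance factor), Sp6, Spp1, Col12a1, Mtap1b, Col18a1, Vdr (the vitamin D receptor), D4Bwg0951e, Plod2 (a collagen lysyl hydroxylase) and Cpe. Sstr2 had the largest change among them, at −4.20 ± 0.38 (SE), from 27.3 ± 4.08 CPM in Fgfr3-derived to 1.49 ± 0.51 CPM in Hes1-derived libraries. Of these 15 genes, Sstr2, Spp1, Cdh15 and Sema3a were among the 19 lower genes after scaling to eGFP. The 15 higher genes with the smallest p had log2 fold changes between 2.06 and 3.54, each with an adjusted p of 0.013. Cd22, Cecr2, Pou2af1, Ms4a1 and Vpreb3 among them belong to the preset B lymphocyte list, and Spna1, an erythrocyte spectrin, to the erythroid list. The others were Irf4, Faim3, Rsad2, Egfl6, Tnfrsf13c, Rhoh, Ccl6, Slfn14-ps and Ifi27l2a. These are in no preset blood-cell list, which does not exclude blood cells as the source of their reads. Egfl6, a secreted matrix-associated protein, had the largest change among them at 3.54 ± 0.38 (SE), with 14.1 ± 0.93 CPM against 1.20 ± 0.083 CPM.

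Pre-osteoblast and osteoblast genes had the lowest median of the biology lists. Of 29 tested members, 17 were lower, none was higher, and 28 had a negative log2 fold change, with a median of −1.67. Adjusted over the list alone, 24 were lower. The master regulator Sp7 fell 4.72-fold, from 157 ± 26.7 CPM in Fgfr3-derived to 33.3 ± 5.03 CPM in Hes1-derived libraries (log2 fold change −2.24 ± 0.24, adjusted p = 0.013). Cdh15 showed −3.90 ± 0.37, Spp1 −3.72 ± 0.36 and Mmp13 −3.47 ± 0.37. Runx2 (−1.46), Alpl (−1.92) and Ibsp (−1.49), named after their values were seen, also passed the test. Col1a1 did not pass (−1.64 ± 0.44, adjusted p = 0.056), and neither did the osteocalcin gene Bglap (−1.22, adjusted p = 0.11), whose reads are uncertain because of a near-identical copy. The list differed from other genes by camera (adjusted p = 1.13e-21; adjusted p = 0.418 with an estimated correlation). Its genes also moved one way by fry (adjusted p = 0.036). The 17 lower calls became 26 with DESeq2 (median −1.65), 9 without Hes1-derived replicate 3 (median −1.61), 3 after scaling to the stroma list (median −1.18) and 3 after scaling to eGFP (median −0.84). Pan-leukocyte markers were higher in the Hes1-derived libraries (median 1.502).

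Among 11 tested osteocyte genes, Enpp1 (−2.03 ± 0.22), Irx5 (−1.96 ± 0.33) and Dmp1 (−2.08 ± 0.53) were lower and none was higher. Adjusted over the list alone, 5 were lower and 3 higher. The median of −0.64 did not separate the list from other genes (camera adjusted p = 0.18), and it was 0.20 after scaling to eGFP, where no osteocyte gene passed. By fry the adjusted p was 0.036. The 3 calls became 2 without Hes1-derived replicate 1, and DESeq2 called 4 lower and 1 higher.

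The genes that define the sort and the 2 lineages were measured in every library. Cxcl12 stood at 7057 and 4180 CPM in Hes1-derived replicates 1 and 3 and at 9764 and 7028 CPM in Fgfr3-derived replicates 2 and 3 (log2 fold change −0.58 ± 0.41, adjusted p = 0.40). The eGFP row followed it, at 6669 and 3204 CPM against 9264 and 6754 CPM (−0.70 ± 0.45, adjusted p = 0.35). Hes1 itself had 69.2 and 41.9 CPM in Hes1-derived libraries and 100.8 and 113 CPM in Fgfr3-derived libraries (−0.94 ± 0.28, adjusted p = 0.068). It passed with DESeq2 (−0.92, adjusted p = 0.020), and its log2 fold change was −1.35 without Hes1-derived replicate 1. Per 1000 eGFP reads, Hes1 had 10.4 and 13.1 reads in Hes1-derived and 10.9 and 16.7 in Fgfr3-derived libraries, so the groups overlapped. Only the Hes1-derived group carries the Cre at a Hes1 allele, and only the Fgfr3-derived group a Cre expressed from Fgfr3. Genotype and origin thus cannot be told apart for Hes1, for Fgfr3 or for any other gene. Fgfr3 had 92.7 and 53.3 CPM against 176 and 147 CPM (−1.14 ± 0.29, adjusted p = 0.049), and lost the call without Hes1-derived replicate 3 (adjusted p = 0.20) and without Fgfr3-derived replicate 2 (adjusted p = 0.13), with non-robust dispersions (adjusted p = 0.0503), and after scaling to the stroma list (adjusted p = 0.55) and to eGFP (adjusted p = 0.73). The iCre-ERT2 row, named after its values were seen, was lower in Hes1-derived libraries, at 24.4 and 16.3 CPM against 95.4 and 74.7 CPM (−2.06 ± 0.28, adjusted p = 0.016), a call that ended after scaling to the stroma list (adjusted p = 0.086) and to eGFP (adjusted p = 0.35). The genotype labels name CreER in the Hes1 line and iCreER in the Fgfr3 line, so the row need not measure both alike. The tdTomato-WPRE row had 229 and 113 CPM against 382 and 510 CPM (−1.39 ± 0.36, adjusted p = 0.04998), and its call ended when Hes1-derived replicate 3 (adjusted p = 0.17), Fgfr3-derived replicate 2 (adjusted p = 0.072) or Fgfr3-derived replicate 3 (adjusted p = 0.097) was left out, with RLE factors (adjusted p = 0.0511), with non-robust dispersions (adjusted p = 0.0505), and after scaling to the stroma list (adjusted p = 0.37) and to eGFP (adjusted p = 0.54). Lepr (−0.71 ± 0.38, adjusted p = 0.27) and Kitl (−0.54 ± 0.47, adjusted p = 0.49) did not pass. After scaling to eGFP the log2 fold change of Cxcl12 was 0.17, of Lepr 0.16 and of Kitl 0.47. Since GFP reports the Cxcl12 locus, a value near 0 for Cxcl12 follows in part from that scaling. The stroma list holds Cxcl12, Lepr and Kitl themselves, so scaling to it draws them towards 0. Kitl also turned to 0.20 after scaling to the stroma list and to 0.49 without Fgfr3-derived replicate 2, and passed without Fgfr3-derived replicate 3 (−1.08, adjusted p = 0.038).

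Of 28 tested CAR cell genes, Csf1 (−1.24 ± 0.25) and Foxc1 (−1.28 ± 0.29), a transcription factor of these cells, were lower and none was higher, while DESeq2 called 7 lower and voom 4. The median of the list was −0.59 in the main test and 0.22 after scaling to eGFP, where no member passed. Camera called it lower than other genes (adjusted p = 0.0023; adjusted p = 0.534 with an estimated correlation), but not without Hes1-derived replicate 3 (adjusted p = 0.10) or Fgfr3-derived replicate 2 (adjusted p = 0.31). Of 26 haematopoietic niche factors, Spp1, Lifr (−1.91 ± 0.32) and Csf1 were lower, and DESeq2 called 4 lower and 1 higher. Their median was −0.56 in the main test, 0.085 after scaling to the stroma list and 0.35 after scaling to eGFP, and the list passed camera (adjusted p = 0.041; adjusted p = 0.534 with an estimated correlation) but not without Hes1-derived replicate 3 (adjusted p = 0.24) or Fgfr3-derived replicate 2 (adjusted p = 0.57). The stroma list is the CAR cell list without Ebf1, and shares Cxcl12, Kitl, Il7, Angpt1, Csf1, Vcam1 and Bmp4 with the niche list. The move of the niche median towards 0 under stroma scaling is therefore partly built in. Adjusted over each list alone, 2 CAR cell genes and 3 niche factors were lower. Without Hes1-derived replicate 1 and without Fgfr3-derived replicate 3, 6 and 7 CAR cell genes were lower, and without Fgfr3-derived replicate 3, 8 niche factors were lower; the niche median was 0.19 without Fgfr3-derived replicate 2. Against these lists, pan-leukocyte markers were higher (median 1.502). Without Hes1-derived replicate 3 no CAR cell gene was lower, and without Fgfr3-derived replicate 2 none was lower and 1 was higher.

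Genes of several developmental signalling pathways were lower in Hes1-derived libraries. Of 21 FGF pathway genes 8 were lower and none higher (median −1.14), including the receptor Fgfr1 (−1.69 ± 0.32) and the FGF-responsive genes Etv4 (−4.20 ± 0.63), Spry4 (−1.32 ± 0.26) and Etv5 (−1.14 ± 0.26). Of 15 Hedgehog pathway genes 5 were lower (median −1.15), among them Kif7 (−1.87 ± 0.36), Gas1 (−1.15 ± 0.23) and the transducer Smo (−1.09 ± 0.23). Of 45 BMP and TGF-beta pathway genes 16 were lower (median −0.91), led by Ctgf (−2.47 ± 0.28), Id4 (−1.76 ± 0.26), Bmp2 (−1.75 ± 0.26) and Bmpr1a (−1.48 ± 0.23). Of 36 WNT pathway genes 8 were lower and 1 higher (median −0.91): Wnt4 (−1.87 ± 0.29), Nkd2 (−1.88 ± 0.33), Apcdd1 (−2.30 ± 0.45) and Wnt5a (−2.12 ± 0.44) were lower and Lgr5 (1.81 ± 0.42) was higher. Adjusted over each list alone, 12 FGF, 9 Hedgehog, 20 BMP and TGF-beta and 17 WNT genes were lower, and 1 Hedgehog, 1 BMP and TGF-beta and 1 WNT gene were higher. These 4 lists passed camera (adjusted p = 2.44e-06 for FGF, 0.0011 for Hedgehog, 2.70e-07 for BMP and TGF-beta and 3.28e-05 for WNT). With an estimated correlation the adjusted p was 0.418 for FGF and WNT and 0.470 for Hedgehog and BMP and TGF-beta.

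These pathway counts moved with the libraries and the scaling, and pan-leukocyte markers were higher in the same libraries (median 1.502). The 8 FGF, 5 Hedgehog, 16 BMP and TGF-beta and 8 WNT genes became 1, 1, 2 and 2 without Hes1-derived replicate 3 (medians −0.91, −1.15, −0.66 and −0.83) and 1, 1, 6 and 2 without Fgfr3-derived replicate 2 (medians −0.78, −0.98, −0.74 and −0.75), and the FGF count became 5 without Hes1-derived replicate 1. DESeq2 called 9 Hedgehog and 17 WNT genes lower. Lgr5 lost its call in the fits without Hes1-derived replicate 3, Fgfr3-derived replicate 2 and Fgfr3-derived replicate 3. After scaling to eGFP, 1 FGF gene and none of the other 3 lists passed as lower, with medians of −0.34 for FGF, −0.32 for Hedgehog, −0.11 for BMP and TGF-beta and −0.08 for WNT. Of 30 Notch pathway genes, Hey1 (−2.26 ± 0.29), Heyl (−1.54 ± 0.22), Hey2 (−2.58 ± 0.51) and Notch3 (−1.38 ± 0.27) were lower, the first 3 being transcriptional targets of the pathway, and Dtx1 (3.03 ± 0.43), a ubiquitin ligase also used by B cells, was higher. Adjusted over the list alone the counts were the same. As a list they did not differ from other genes (camera adjusted p = 0.30), and the median of −0.27 turned to 0.29 and 0.59 after scaling to the stroma list and to eGFP, where only Dtx1 passed. Without Hes1-derived replicate 3 and without Fgfr3-derived replicate 2, 2 Notch genes were lower, and without Fgfr3-derived replicate 3, 4 were higher. DESeq2 called 4 Notch genes higher and 5 lower.

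Matrix genes were lower as a group, in libraries where pan-leukocyte (median 1.502) and B lymphocyte markers (median 2.30) were higher. Of 49 fibrillar and basement membrane matrix genes 21 were lower and 2 higher (median −1.13, camera adjusted p = 1.46e-13; adjusted p = 0.418 with an estimated correlation). Col12a1 showed −2.10 ± 0.21, Col18a1 −2.22 ± 0.22, Col5a2 −1.67 ± 0.22 and Fbn2 (fibrillin 2) −2.28 ± 0.33. The higher members were the microfibril genes Mfap4 (2.85 ± 0.63) and Mfap5, which had 84 reads in Hes1-derived and 3 reads in Fgfr3-derived libraries, a ratio of 30.3 with a 95% counting interval of 10.03 to 150.1. Mfap5 lost its call without Hes1-derived replicate 3, Fgfr3-derived replicate 2 or Fgfr3-derived replicate 3. The counts adjusted over the list alone were 34 lower and 4 higher. The 21 lower calls became 34 with DESeq2, 7 without Hes1-derived replicate 3 (median −0.84), 11 without Fgfr3-derived replicate 2 (median −1.07), 4 after scaling to the stroma list and none after scaling to eGFP (median −0.42). Of 23 skeletal stem and progenitor cell markers 10 were lower, among them Hoxa11 (−2.50 ± 0.44), Acta2 (−1.53 ± 0.24), Itga5 (−1.08 ± 0.20) and Itgav (−1.43 ± 0.26), and Ly6a, the gene of SCA-1, was higher (1.73 ± 0.35). Their median was −1.08 (camera adjusted p = 7.41e-06; adjusted p = 0.418 with an estimated correlation), with 14 lower and 1 higher when adjusted over the list alone. The 10 lower calls became 1 without Hes1-derived replicate 3 (median −1.10), 2 without Fgfr3-derived replicate 2 (median −0.79) and none after scaling to eGFP (median −0.22).

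Perichondrial, periosteal and fibroblast genes went both ways in these libraries, which differed in pan-leukocyte markers (median 1.502). Of 27 tested, Mfap5, Ly6a and Col14a1 (2.88 ± 0.59) were higher and 6 were lower, with Col12a1, Fap (−1.79 ± 0.26), Postn (−1.36 ± 0.24) and the limb mesenchyme factor Prrx1 (−1.49 ± 0.28) having the smallest p. Adjusted over the list alone, 6 were higher and 9 lower, and DESeq2 called 6 higher and 8 lower. The median was −0.23 and the mean 0.03, so that they differed in sign, and camera did not separate the list from other genes (adjusted p = 0.27). The median turned to 0.18 after scaling to the stroma list and 0.44 after scaling to eGFP, where 5 and 3 members were higher and none lower, and to 0.097 without Hes1-derived replicate 3 and 0.077 without Fgfr3-derived replicate 3. Without Hes1-derived replicate 3 none was higher and 2 were lower, and without Fgfr3-derived replicate 2 none was higher and 3 were lower. Of 23 Hox genes Hoxa11, Hoxb2 (−2.06 ± 0.48) and Hoxb5 were lower and 22 had a negative log2 fold change (median −1.17, camera adjusted p = 1.95e-05; adjusted p = 0.470 with an estimated correlation), with 6 lower when adjusted over the list alone. Hoxb5 had no read in the Hes1-derived libraries and 36 in the Fgfr3-derived libraries, so that it was at least 5.54-fold lower against a floor of 3 reads per library. DESeq2 called 7 Hox genes lower. None was lower without Hes1-derived replicate 3 (list median −0.90) or after scaling to eGFP (median −0.35), 1 was lower without Fgfr3-derived replicate 2 and 2 without Fgfr3-derived replicate 3.

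Cell cycle genes were higher in Hes1-derived libraries. All 40 tested members had a positive log2 fold change and 26 passed (median 0.95, camera adjusted p = 9.80e-17; adjusted p = 0.418 with an estimated correlation). Mki67 showed 1.42 ± 0.20, Cdk2 1.15 ± 0.21, Ube2c 1.32 ± 0.24 and Ccne1 1.12 ± 0.21. As many as 36 were higher when adjusted over the list alone. The 26 calls became 7 without Hes1-derived replicate 1 (median 1.02), 2 without Hes1-derived replicate 3 (median 0.85), 1 without Fgfr3-derived replicate 2 (median 0.80), 3 after scaling to the stroma list and none after scaling to eGFP, although the median then rose to 1.45 and 1.78. The B lymphocyte and erythroid markers, from cell types that divide in marrow, were higher in the same libraries (medians 2.30 and 1.69). Nuclear oxidative phosphorylation genes had a median of 0.28 over 42 members and 36 positive values, but only Cox7b passed (1.10 ± 0.21, also when adjusted over the list alone). The list passed camera (adjusted p = 0.0096; adjusted p = 0.534 with an estimated correlation), though not without Fgfr3-derived replicate 2 (adjusted p = 0.067). Cox7b passed in neither the fit without Hes1-derived replicate 3 nor that without Fgfr3-derived replicate 2.

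Of 39 interferon response genes, Rsad2 (viperin, 2.92 ± 0.29) and the oligoadenylate synthetases Oas3 (2.52 ± 0.30), Oas2 (2.02 ± 0.45) and Oas1a (2.11 ± 0.53) were higher and none was lower, also when adjusted over the list alone. The median was 0.25, and other members such as Ifit1 (0.43, adjusted p = 0.75), named after its values were seen, did not pass. Camera called the list (adjusted p = 0.0021; adjusted p = 0.534 with an estimated correlation), but without Fgfr3-derived replicate 3 it did not (adjusted p = 0.52, median −0.00079). Without Hes1-derived replicate 3, 2 members were higher, and without Fgfr3-derived replicate 2, 7 were, and DESeq2 called 10. B lymphocyte and pan-leukocyte markers were higher in the same libraries (medians 2.30 and 1.502).

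All 23 cholesterol synthesis genes had a negative log2 fold change, beside higher pan-leukocyte markers (median 1.502), and 5 were lower, including Cyp51 (−1.24 ± 0.20), Hmgcs1 (−1.26 ± 0.23) and Sqle (−1.03 ± 0.25). Their median of −0.51 (camera adjusted p = 0.000157; adjusted p = 0.418 with an estimated correlation) turned to 0.0088 and 0.31 after scaling to the stroma list and to eGFP, where none passed. Adjusted over the list alone, 5 were lower. The count became 3 without Hes1-derived replicate 1, none without Hes1-derived replicate 3 (median −0.58), 1 without Fgfr3-derived replicate 2 (median −0.64) and 3 without Fgfr3-derived replicate 3. Of 28 glycolysis and hypoxia genes P4ha2 (−1.60 ± 0.21) and Vegfa (−1.35 ± 0.25) were lower, also when adjusted over the list alone, with a list median of −0.04 that was 0.50 and 0.82 under those scalings and 0.03 with library totals (camera adjusted p = 0.27). The 2 calls became 5 with DESeq2, 1 without Hes1-derived replicate 3 or Fgfr3-derived replicate 2, and 5 lower and 3 higher without Fgfr3-derived replicate 3 (median 0.060, and 0.042 without Hes1-derived replicate 1). Of 25 adipocyte-lineage and lipid genes Cd36 (1.79 ± 0.24) and Acsl1 (1.13 ± 0.21), which take up and activate fatty acids, were higher, while 5 were lower, among them Scd2 (−1.31 ± 0.20), Zfp423 (−1.57 ± 0.25), Gpd1 (−2.28 ± 0.38) and the lipid droplet gene Plin1 (−2.92 ± 0.65). Their median of −0.43 turned to 0.22 and 0.45 under the scalings to stroma and to eGFP (camera adjusted p = 0.090), and adjusted over the list alone 3 were higher and 7 lower. The 2 higher and 5 lower genes became 1 and 3 without Hes1-derived replicate 1, 1 and 0 without Hes1-derived replicate 3, 1 and 1 without Fgfr3-derived replicate 2 and 3 and 6 without Fgfr3-derived replicate 3, where camera called the list lower (adjusted p = 0.013).

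**Figure D2:**
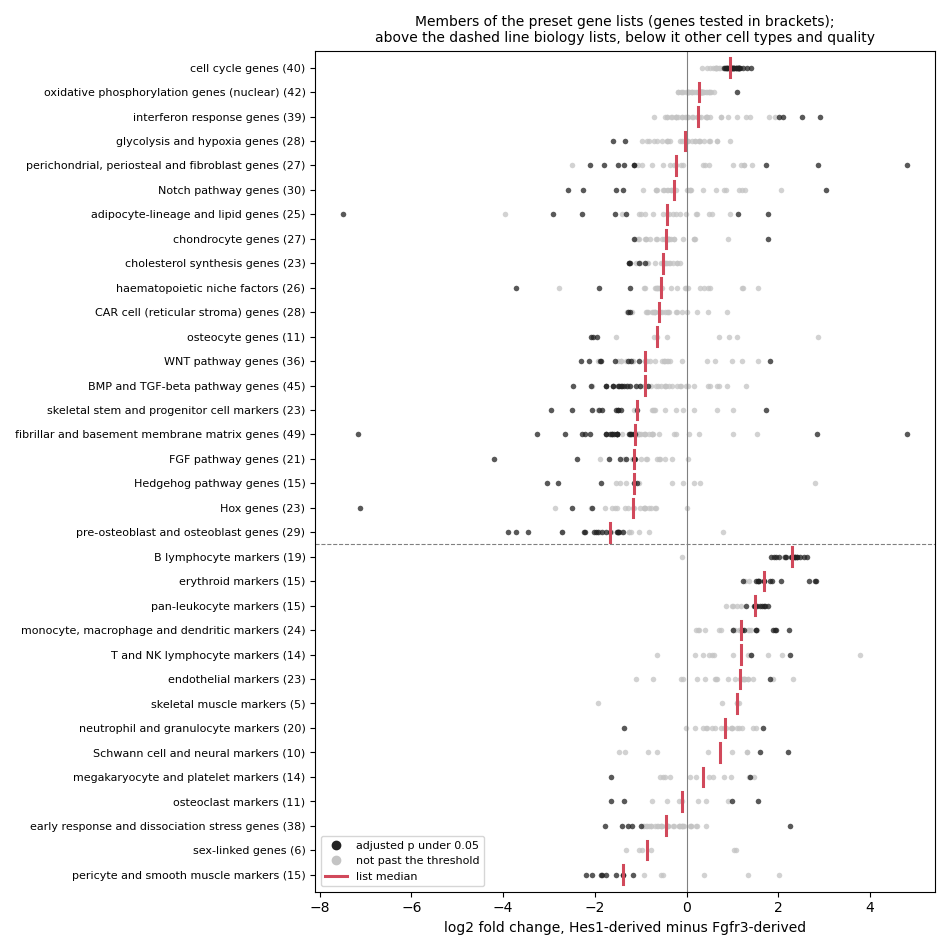
Log2 fold change (Hes1-derived minus Fgfr3-derived) of each tested member of the 34 tested gene lists, dark where the adjusted p is under 0.05, with a red bar at each list median. Osteoblast genes have the lowest median (−1.67) and B lymphocyte markers the highest (2.30). The osteoblast median stays below 0 under the scalings to stroma and to eGFP, while 12 list medians change sign under eGFP and 9 under stroma scaling. The 3 points below −7 are fitted values of genes with no read in the Hes1-derived libraries.

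Markers of blood cells were present in all libraries and higher in the Hes1-derived libraries, although a sort for GFP and tdTomato should exclude them. Whether GFP was also gated is open, and a sort for tdTomato alone need not exclude them. Of 19 B lymphocyte markers 17 were higher (median 2.30), including Cd22 (2.47 ± 0.26) and Pou2af1 (2.30 ± 0.26), and the abundant Cd79a stood at 728 and 623 CPM against 86.4 and 166 CPM. Of 15 erythroid markers 13 were higher (median 1.69), with Alas2, the haem synthesis gene of red cells, at 3838 and 1870 CPM against 367 and 535 CPM. Of 15 pan-leukocyte markers 10 were higher (median 1.502), led by Cytip (1.78 ± 0.29) and Laptm5 (1.70 ± 0.29), and of 24 monocyte, macrophage and dendritic markers 9 were higher (median 1.19), led by H2-Aa (1.89 ± 0.23), H2-Ab1 (1.96 ± 0.28) and Cd74 (2.23 ± 0.33). Of 14 T and NK lymphocyte markers Il7r (2.27 ± 0.28) and Lck (1.41 ± 0.33) were higher (median 1.18). Of 20 neutrophil markers Mmp8 (1.67 ± 0.41) was higher and Mmp9 (−1.36 ± 0.29) lower (median 0.85), and Ngp stood at 8972 and 10199 CPM against 2618 and 7235 CPM (adjusted p = 0.26). Adjusted over each list alone, 18 B lymphocyte, 15 erythroid, 12 pan-leukocyte, 18 monocyte, 5 T and NK and 2 neutrophil markers were higher and 1 neutrophil marker lower.

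These 6 blood lists passed camera, with adjusted p = 2.28e-27 for B lymphocyte, 1.24e-16 for erythroid, 6.69e-11 for pan-leukocyte and monocyte and 0.00065 for T and NK and neutrophil markers. With an estimated correlation the adjusted p was 0.364 for all but the neutrophil markers, where it was 0.577. Fgfr3-derived replicate 2 had the lowest level of each of the 6 lists, with a mean log2 CPM of 6.39 for pan-leukocyte markers against 7.38 in Fgfr3-derived replicate 3. Without Fgfr3-derived replicate 3, 14 neutrophil, 14 monocyte, 15 pan-leukocyte and 5 T and NK markers were higher. Without Fgfr3-derived replicate 2, the counts were 0 neutrophil, 3 monocyte, 1 pan-leukocyte, 1 T and NK and 4 erythroid markers, and the neutrophil list lost its camera call (adjusted p = 0.073). Without Hes1-derived replicate 1 they were 0 neutrophil, 6 pan-leukocyte, 1 T and NK and 8 erythroid markers, and without Hes1-derived replicate 3 they were 0 neutrophil, 3 monocyte, 1 pan-leukocyte and 1 T and NK marker. The B lymphocyte count stayed between 13 and 16 in these 4 fits. After scaling to eGFP, 16 B lymphocyte, 5 erythroid, 3 pan-leukocyte, 4 monocyte, 2 T and NK and 1 neutrophil marker were higher, and DESeq2 called 18 monocyte, 7 neutrophil and 4 T and NK markers higher.

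Other marker lists were smaller or split. Of 15 pericyte and smooth muscle markers 9 were lower (median −1.38, camera adjusted p = 1.56e-05; adjusted p = 0.364 with an estimated correlation), led by Abcc9 (−2.19 ± 0.27), Acta2, Mcam (−1.85 ± 0.34) and Cspg4 (−2.06 ± 0.39), and adjusted over the list alone 10 were lower and 1 higher. The 9 calls became 1 without Hes1-derived replicate 3 (median −1.21), 4 without Fgfr3-derived replicate 2 (median −1.32), 6 without Fgfr3-derived replicate 3 and none after scaling to eGFP (median −0.55). Of 23 endothelial markers only Pecam1 passed (1.81 ± 0.25, also when adjusted over the list alone), where DESeq2 called 7 higher and 1 lower and stroma scaling gave 4 higher, with a median of 1.17 (camera adjusted p = 0.00065; adjusted p = 0.364 with an estimated correlation), and without Hes1-derived replicate 1 and Fgfr3-derived replicate 3 the higher calls were 2 and 4. Of 38 early response and dissociation stress genes 5 were lower, including Maff (−1.78 ± 0.26), Klf4 (−1.40 ± 0.21), Fosb (−0.99 ± 0.20) and Cyr61 (−1.28 ± 0.32), and Dusp2 was higher (2.25 ± 0.35), with 7 lower and 1 higher when adjusted over the list alone. The median of −0.45 (camera adjusted p = 0.0025; adjusted p = 0.364 with an estimated correlation) turned to 0.099 and 0.35 under the scalings to stroma and to eGFP, and the 5 lower calls became 10 with DESeq2, 7 without Fgfr3-derived replicate 3, 3 without Hes1-derived replicate 1 or Fgfr3-derived replicate 2 and 1 without Hes1-derived replicate 3.

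Camera did not call the other lists. Of 14 megakaryocyte markers Gata1 (1.40 ± 0.25) was higher and Itgb3 (−1.65 ± 0.24) lower (median 0.35, adjusted p = 0.35; 2 higher with DESeq2), and of 11 osteoclast markers Car2 (1.57 ± 0.34) and Acp5 (0.99 ± 0.23) were higher and Itgb3 and Mmp9 lower (median −0.09, 0.60 and 1.04 under the scalings to stroma and to eGFP, adjusted p = 0.55). Car2 is also in the erythroid list, Itgb3 in the megakaryocyte list and Mmp9 in the neutrophil list, so these calls are not specific to osteoclasts. Of 10 Schwann cell and neural markers Mbp (1.61 ± 0.30) and Gfap (2.22 ± 0.46) were higher (median 0.73, adjusted p = 0.26), and none of 5 skeletal muscle markers passed (median 1.11, adjusted p = 0.36). Adjusted over each list alone, 2 megakaryocyte, 2 osteoclast and 2 Schwann markers were higher, 1 megakaryocyte and 3 osteoclast markers were lower, and no muscle marker passed. No Schwann marker passed without Fgfr3-derived replicate 2 and 1 without Hes1-derived replicate 1. No osteoclast marker passed without Hes1-derived replicate 3, where the list itself passed (adjusted p = 0.0057, median −1.48), and the megakaryocyte list, with medians between −0.44 and 1.08 over the fits without 1 library, passed without Hes1-derived replicate 3 (adjusted p = 0.047) and without Fgfr3-derived replicate 2 (adjusted p = 0.0038). None of 6 sex-linked genes passed, while DESeq2 and voom each called 1 lower (median −0.87, 0.14 after scaling to eGFP, adjusted p = 0.35). Xist, expressed from the inactive X of females, had 52.4 and 55.4 CPM in Hes1-derived replicates 1 and 3, 50.6 CPM in Fgfr3-derived replicate 2 and 0.15 CPM in Fgfr3-derived replicate 3. The Y-linked Ddx3y was read in every library, at 22.4, 50.7, 93.7 and 87.9 CPM in the same order. The balance of Xist and Y-linked reads thus differed between libraries, and the labels used here do not give the sex of the animals. Reads of both Xist and Ddx3y point to RNA of both sexes, and so of more than 1 animal, in Hes1-derived replicates 1 and 3 and Fgfr3-derived replicate 2. Fgfr3-derived replicate 3, with Ddx3y and almost no Xist, points to male RNA. The sex-linked list passed without Hes1-derived replicate 3 (adjusted p = 0.0040, median −1.56, 1 gene lower) and without Fgfr3-derived replicate 2 (adjusted p = 0.0014, median −1.10, 2 genes higher).

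Chondrocyte genes differed more between libraries of a group than between the groups. Of 27 tested, the transcription factor Sox6 was higher (1.77 ± 0.25) and Fgfr3 lower, the median was −0.44, and the list did not differ from other genes (camera adjusted p = 0.65). Sox6 was the only call when adjusted over the list alone, while 22 of the 27 members had a negative log2 fold change. Erythroid markers were higher in the same libraries (median 1.69), and whether the Sox6 reads came from stromal cells was not tested. Col2a1, the main cartilage collagen, stood at 523 and 1951 CPM in Hes1-derived replicates 1 and 3 and at 3162 and 410 CPM in Fgfr3-derived replicates 2 and 3. Acan (aggrecan), with 5.76 and 38.8 CPM against 56.2 and 1.72 CPM, and Comp, with 39.0 and 134 CPM against 220 and 7.45 CPM, had the same order, and all 3 were named after their values were seen. The list median was 1.78 higher in Hes1-derived replicate 3 than in replicate 1, with 22 of 27 genes higher, and 2.95 higher in Fgfr3-derived replicate 2 than in replicate 3, with 25 of 27 genes higher. The median between the groups was 1.83 without Fgfr3-derived replicate 2 and 0.13 without Hes1-derived replicate 1, and 0.49 and 0.83 after scaling to the stroma list and to eGFP. It was also positive with limma-voom (0.16) and with limma-trend on the deposited signal (0.17). The list passed camera without Fgfr3-derived replicate 2 (adjusted p = 0.00051, median 1.83), without Fgfr3-derived replicate 3 (adjusted p = 0.00055, median −1.21) and without Hes1-derived replicate 3 (adjusted p = 0.047, median −1.71).

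**Figure D3:**
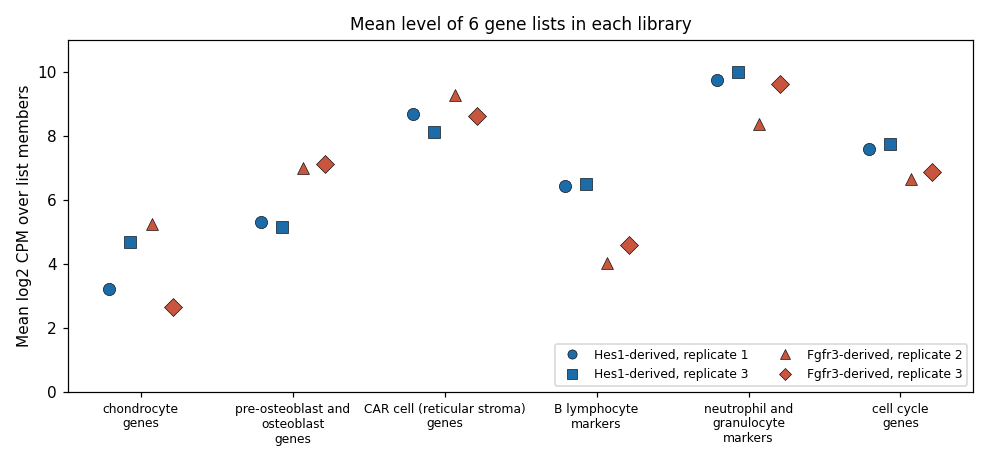
Mean log2 CPM over the tested members of 6 gene lists, with a symbol for each of the 4 libraries. Chondrocyte genes are highest in Fgfr3-derived replicate 2 (5.23) and lowest in Fgfr3-derived replicate 3 (2.65), while both osteoblast values of the Fgfr3-derived libraries (6.98 and 7.11) lie above those of the Hes1-derived libraries (5.31 and 5.15). B lymphocyte and cell cycle genes separate the groups in the other direction.

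Over all lists, camera called 14 of the 20 biology lists, 3 of them higher and 11 lower in Hes1-derived libraries, and 9 of the 14 lists of other cell types and quality, 7 higher and 2 lower. With an estimated correlation, which leaves 2 residual degrees of freedom, it called 0 lists in either family, with smallest unadjusted p-values of 0.025 and 0.047. Fry called the osteoblast and osteocyte lists and no list of other cell types.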

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

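The scalings to stroma and to eGFP and the leukocyte covariate were chosen after seeing the data, and all other alternatives before. No paired analysis was possible because the groups share only replicate number 3. List tests were not rerun without the genes of other cells or with DESeq2. The cause of the changes below was not tested.

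The gene counts stayed within 1.5 times the main counts, at 734 to 917 higher and 899 to 1049 lower, with RLE, upper-quartile and library-total scaling, voom, limma-trend, both other filters, non-robust dispersions and the removal of genes of other cells. Low read depth bears on genes such as Mfap5 and Hoxb5, which have few reads. DESeq2 called 1429 higher and 1557 lower genes, and an adjusted p under 0.10 called 1411 and 1664. Scaling to stroma gave 688 higher and 102 lower genes, of which 602 were also main calls. Scaling to eGFP gave 324 higher and 19 lower, of which 287 were also main calls. The covariate, which correlates with the group (r = 0.897), gave 4 and 4, of which 3 were called without it. Leaving out 1 library gave 183 higher (without Fgfr3-derived replicate 2) to 1225 higher (without Fgfr3-derived replicate 3), and 181 lower (without Hes1-derived replicate 3) to 998 lower (without Fgfr3-derived replicate 3). Camera called 14 biology and 9 other lists. With an estimated correlation it called 0 biology and 0 other lists, and fry called 2 and 0. With the covariate it called 10 biology lists (5 up, 5 down) and 5 other lists, not all of them main calls. Against the main test, 6 lists then changed direction, and of the rest 10 lost and 2 gained a call. The niche list lost its call with voom, stroma and eGFP scaling, and the early response list with eGFP scaling, while adipocyte genes became called lower than other genes with stroma and eGFP scaling, although their medians were then positive (0.22 and 0.45). Camera likewise called the CAR cell and cholesterol lists lower than other genes with eGFP scaling, where their medians were 0.22 and 0.31.

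Hes1 passed with DESeq2 (−0.92, adjusted p = 0.020) and ranged from −1.35 (without Hes1-derived replicate 1) to −0.62 over the fits without 1 library. Its reads per 1000 eGFP reads overlapped between the groups (10.4 and 13.1 in Hes1-derived against 10.9 and 16.7 in Fgfr3-derived libraries). Cxcl12 turned to 0.17 with eGFP scaling and 0.37 with the covariate. With the covariate, which tracks the group, the direction of these lists by camera reversed: CAR cell (median 0.47), niche (0.73), chondrocyte (3.78), neutrophil (−0.94), T and NK (−0.56) and adipocyte genes, whose median stayed negative (−0.35). Glycolysis (−0.30) and megakaryocyte lists (2.35) became called. Without Hes1-derived replicate 1 the chondrocyte (0.13) and osteoclast (0.73) lists reversed in direction by camera. Without Fgfr3-derived replicate 2 the chondrocyte (1.83) and sex-linked lists did, the latter with a median that stayed negative (−1.10). Without Fgfr3-derived replicate 3 the megakaryocyte list (−0.42) did. Lists with medians of −1.71 (chondrocyte), −1.48 (osteoclast) and −1.56 (sex-linked) became called without Hes1-derived replicate 3, and the megakaryocyte list (1.08) without Fgfr3-derived replicate 2.

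Under the covariate these genes changed sign: Mmp8 (−0.0497), Ngp (−0.95), Ltf (−0.92), Nkg7 (−1.23), Lyz2 (−0.44), Arhgdib (−0.69), Lcp1 (−0.72), Nfe2 (−0.12), Mpo (−0.94), Clec14a (0.37), Eng (0.20), Mylk (0.26), Lepr (1.02), Kitl (1.81), eGFP (0.33) and Igfbp4 (0.055). Under eGFP scaling Eng (0.083), Eif2s3y (0.25), Lepr (0.16), Kitl (0.47) and Uty (0.041) did, and Kitl also with stroma scaling (0.20) and without Fgfr3-derived replicate 2 (0.49). Kitl passed without Fgfr3-derived replicate 3 (−1.08).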

Other observations

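Genes that share a symbol stem were grouped after the results were seen, and 300 one-sided Fisher's exact tests over 150 families were adjusted by Benjamini-Hochberg. Fisher's test treats genes as independent, so its p-values are too small where genes of a family move together. The matrix gene list, which shares collagens with the first family below, had an adjusted p of 0.418 by camera with an estimated correlation. Collagen genes were called lower in Hes1-derived libraries in 13 of 38 cases (adjusted p = 0.000134), among them the basement membrane collagens Col4a1, Col4a2 and Col4a5, and higher in 3 (Col14a1, Col8a2 and Col6a5). Matrix metalloproteinases were lower in 8 of 16 cases (adjusted p = 0.000267): Mmp13, Mmp11, Mmp16, Mmp14, Mmp17, Mmp9, Mmp2 and Mmp10, with Mmp8 higher. Tetraspanins, membrane proteins that organise adhesion receptors, were lower in 8 of 19 cases (adjusted p = 0.000984) and higher in 4 (Tspan8, Tspan13, Tspan33 and Tspan32; adjusted p = 0.287). The class I and II histocompatibility genes were higher in 10 of 29 cases (adjusted p = 0.000178), including H2-Ob and the monocyte and dendritic list members H2-Aa and H2-Ab1, in libraries where B lymphocyte (median 2.30) and pan-leukocyte markers (median 1.502) were also higher, and H2-Q6 was lower. Tripartite motif genes (Trim, 10 of 42, adjusted p = 0.0028, with Trim47 lower) and replication licensing genes (Mcm, 5 of 10, adjusted p = 0.0039), all 5 of them members of the cell cycle list, were also higher in those libraries. Semaphorins were lower in 6 of 18 cases (Sema, adjusted p = 0.031) and higher in 3 (Sema4d, Sema4b and Sema3g; adjusted p = 0.78). Among the 19 genes lower after scaling to eGFP, Mmp13 was the only metalloproteinase, Col13a1 the only collagen and Sema3a the only semaphorin, and none was a tetraspanin. After the same scaling no cell cycle gene, and so none of the 5 Mcm genes, was called higher. The cell cycle median nevertheless rose from 0.95 to 1.78, so the lost calls do not show a smaller difference.

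The tests in this part were chosen after the result was seen, except the second chondrocyte list and the Hes1 locus, whose tests were written before their values were computed. Intervals are 95% bootstrap intervals over genes and do not measure the variation between animals.

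Lower osteoblast genes in Hes1-derived libraries have 3 candidate explanations. Dilution of stromal RNA by blood-cell RNA alone predicts equal falls of osteoblast and reticular stroma genes, if blood cells add no reads of either. The osteoblast median minus the stroma median was −1.074 (−1.386 to −0.784, and −1.695 to −0.519 over the 4 library pairs). Under that condition, which was not tested, this speaks against dilution as the whole explanation. Relative to eGFP the list median was −0.955, −1.67 and −0.846 in 3 pairs, but for Hes1-derived replicate 3 against Fgfr3-derived replicate 2 the value was −0.211 (−0.88 to 0.279). Spp1, Mmp13 and Cdh15 had a largest adjusted p of 0.0398 after scaling to eGFP, but they were picked after their large changes were seen, so this adds no weight against dilution. A sort for GFP and tdTomato should remove mature osteoblasts, but a sort for tdTomato alone, which the extraction protocol names, need not. Their carry-over into the Fgfr3-derived sort predicts a larger fall of late than of early genes. The late minus early median was 0.378 (−0.13 to 0.98), which leaves it open, and a lineage difference stays open and untested.

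Higher blood-cell and cell cycle genes may come from blood cells in the sort, which a clean gate on GFP and tdTomato would remove. The extraction protocol names tdTomato alone, and such a sort need not remove them. The most abundant B lymphocyte and neutrophil genes included Cd79a (728 and 623 CPM against 86.4 and 166 CPM) and Ngp. A lower share of stromal cells alone predicts that each blood-cell type rises alike. The B lymphocyte median exceeded the neutrophil median by 1.452 (1.182 to 1.823, and 0.836 to 1.765 over the 4 library pairs), which speaks against an equal rise. Blood-cell types did not move alike within a group either: Fgfr3-derived replicate 3 minus 2 was 1.335 for neutrophil and 0.697 for B lymphocyte markers. A lower stromal share with a varying mix of blood cells thus stays open. Of the list genes, Ebf1 in the B lymphocyte list and Mmp9 in the neutrophil list are also in other lists. With the pan-leukocyte covariate the cell cycle median was 0.566 (0.379 to 0.71), but the covariate correlates with group (r = 0.897), so that cell cycle RNA from blood cells and from dividing stromal cells both stay open.

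Chondrocyte genes differed between libraries of the same group. A gate on GFP and tdTomato and the removal of the distal growth plates should keep out RNA of other chondrocytes. A sort for tdTomato alone, which the extraction protocol names, need not. Such RNA in part of the libraries predicts that a second chondrocyte list of 24 genes moves with the first. The smaller of its within-group medians was 0.0799 (−0.226 to 0.397, Hes1-derived replicate 3 minus 1) and the other 0.517 (−0.122 to 1.374, Fgfr3-derived replicate 2 minus 3), against 1.78 and 2.95 for the preset list, which leaves this open. An exchange of libraries between the groups predicts overlapping iCre-ERT2 levels per eGFP, but the lowest Fgfr3-derived level was 2.021 times the highest Hes1-derived level, which speaks against it.

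Flanking DNA of the Hes1 allele that carries the Cre predicts more calls near Hes1. Within 10 Mb, 13 of 154 genes were called (8.44% against 11.9% elsewhere; odds ratio 0.685, 95% interval 0.355 to 1.213; one-sided Fisher's exact p = 0.93), so that no surplus was detected. Reading this as open, since the interval allows a small surplus, was decided after the value was seen; the prediction written before would have set the explanation aside.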
